A study of Arabidopsis thaliana with 9 samples.

How the data were processed

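The series measured transcript levels in Arabidopsis thaliana, accession Col-0, on Affymetrix 3' expression arrays with 22810 probe sets. Per the labels, 9 arrays were hybridised with RNA from above-ground tissue of 8-week-old greenhouse plants. They fall into 3 groups of 3 biological replicates: wild type, plants with MSH1 suppressed by RNA interference (RNAi) that showed a variegated phenotype, and RNAi plants that showed a stunted phenotype. Groups and replicate numbers were taken from the sample titles.

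The deposited values are log2 expression values, 1 column per array, and the submitters' processing notes name RMA (robust multi-array averaging) and the affy package without versions. The array medians lay between 3.37 and 3.43 and the values between 1.98 and 13.1, with no missing value. This floor is lower than plain RMA usually leaves, and the background step is not given in the sources used here, so the scale near the floor is unknown and changes of dim probe sets can be compressed or stretched. RMA-type processing sets the arrays to nearly the same distribution, so a shift of most transcripts in 1 direction would not be seen. Arrays carry no read depth, and the number of arrays limits the precision.

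From these values, 64 control probe sets were set aside and 22746 probe sets were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted over all 9 arrays, with empirical Bayes moderation, and 3 contrasts were taken: variegated against wild type, stunted against wild type and stunted against variegated. P-values were adjusted with the Benjamini-Hochberg method within each contrast, and an adjusted p under 0.05 passed. All adjusted p-values are limma's, log2 changes carry the moderated standard error (SE), and tests are two-sided. Single values of 3 arrays against 3 were compared with an exact permutation test, whose smallest possible p is 0.1.

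Gene names came from the platform's annotation table, which is old. Of the tested probe sets, 13513 (59.4%) had 1 gene, 503 had several and 8730 were not listed. A probe set with several genes or none was counted in totals and never named. Where a gene had more than 1 probe set, the brightest over all arrays represented it, which left 13355 genes. Of these, 13333 were found by gene number in a reference gene table of assembly TAIR10.1, which was used for names alone. Many well-studied genes lack a listed probe set here, MSH1 among them, so the suppression of MSH1 itself was not analysed here. No genome build is named in the files, and positions are not given.

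Before the data were examined, 41 gene lists were fixed. With 3 or more measured members, 20 could be tested. A further 14 had 1 or 2 members, reported as single genes at most, and 7 had none. The plastid-encoded list was made from locus codes of the reference gene table. The mitochondrion-encoded list was made from platform symbols of genes not found in that table. These symbols began with nad, cox or ccb and a digit, or with matR or orfX. Any mitochondrion-encoded gene with another symbol was left out. Lists were tested on 1 probe set per gene with camera (inter-gene correlation preset at 0.01), with p-values adjusted over the 20 lists. Alternatives were camera with the correlation estimated from the residuals, which is much stricter for lists whose members vary together between arrays, and fry. A further 38 gene families were defined by symbol after the gene table had been opened and before any group difference was computed.

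The named genes followed a rule fixed before the data were examined. It takes, in each comparison, the 8 largest rises and the 8 largest falls among genes that passed and whose arrays did not overlap between the groups. It adds up to 4 members of each list that passed, or the 2 with the smallest p where none did.

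The procedure was tested on simulated arrays with the real means and 200 of 22746 probe sets changed in 1 group. The spreads were those moderated by limma, and the noise was independent between probe sets. That is the noise the test assumes, so the recovery is that of a favourable case. In the simulated variegated against wild type comparison, 62.7% of changes of 0.5 on the log2 scale were recovered, 95.5% of changes of 1 and 98.5% of changes of 2, with 7 false calls among 178. In the simulated stunted against wild type comparison these shares were 53.7%, 89.6% and 100%, with 10 false calls among 172. In the simulated stunted against variegated comparison they were 59.7%, 98.5% and 100%, with 8 false calls among 180. In a simulation on 13355 genes, a list of 16 members raised by 0.4 in the variegated group was the 1 list called of 20. Its members also varied independently, so it does not test the calls of lists whose members vary together between arrays.

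Alternatives fixed before the data were examined covered the replicate number as a block, the 2 compared groups alone, an intensity trend, robust moderation, array weights, median centring, quantile normalization, a filter on the dimmest 30% of probe sets, stricter thresholds, cross-hybridising probe set types left out, an unmoderated test and each array left out in turn. Alternatives added after the data were seen used 3 control signals as covariates (the actin 3' minus 5' signal, the 25S rRNA signal and the mean of the bioB spike-in probe sets), and list members matched by locus code alone. The omissions and covariates were also run on the families called by camera. Comparisons that share the wild-type arrays were set against 100 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9.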

Results

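MSH1 is a nuclear-encoded MutS homologue that acts in mitochondria and plastids, where its loss is known to allow recombination of the organelle genomes. The arrays compared wild-type Arabidopsis with RNAi plants suppressed for MSH1, which were sampled as variegated or as stunted plants, and ask which transcripts accompany each phenotype. Each group held 3 arrays of separate biological replicates from 8-week-old plants. Within a group the arrays correlated at r = 0.9855 to 0.9946 across probe sets (9 pairs), and between groups at 0.9738 to 0.9912 (27 pairs). No pair of arrays was a duplicate. The leading principal component held 43.6% of the variance and separated the groups, with wild type at -26.3 to -19.1, variegated at -9.5 to -0.1 and stunted at 14.8 to 34.1. Within each group it also rose from replicate 1 to replicate 3, the array with the highest actin 3' minus 5' signal of its group. The level of MSH1 was not analysed here, so the labels have no check from the targeted gene.

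In variegated plants, 61 probe sets rose and 40 fell against wild type, of 22746 tested. Of these 101 probe sets, 53 mapped to no single gene and could not be named. The largest rises among the named genes, in AT2G21640 and AT5G09570, were in genes of the mitochondrial stress response. AT2G21640, which encodes a protein induced by oxidative stress and is a marker of mitochondrial dysfunction, rose by 2.55 on the log2 scale (SE 0.21, 5.87-fold, adjusted p = 0.00294), from 3.94 ± 0.19 in wild type to 6.50 ± 0.43 (mean ± SD, n = 3). AT5G09570, a small mitochondrial cysteine-rich protein, rose by 2.47 (SE 0.24, adjusted p = 0.00718). AT1G43590 rose by 2.44 (SE 0.15, adjusted p = 0.00048). AT2G07722, which lies in the copy of the mitochondrial genome inserted in a nuclear chromosome, rose by 1.35 (SE 0.19), and AT3G03270, a universal stress protein, by 1.04 (SE 0.15). Of plastid function, the plastid-encoded ribosomal protein gene rpl20 rose by 1.49 (SE 0.20) and Cpn60beta2, a subunit of the plastid chaperonin, by 1.02 (SE 0.12). The remaining large rise was AT5G43450, an oxygenase gene, at 1.44 (SE 0.16). CCS, the copper chaperone of superoxide dismutase, rose by 0.91 (SE 0.13, adjusted p = 0.024).

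The largest fall in variegated plants was AT2G33850, which fell by 3.18 (SE 0.19, 9.06-fold, adjusted p = 0.00048), from 6.03 ± 0.45 to 2.85 ± 0.15 (n = 3). AT3G11880 fell by 1.58 (SE 0.12) and AT1G54020, a GDSL-type lipase gene, by 1.56 (SE 0.24). AT2G38240, an oxygenase that inactivates jasmonate, fell by 1.52 (SE 0.19). AT3G51450, a strictosidine synthase-like gene, fell by 1.33 (SE 0.22), and GH9B8, an endoglucanase, by 1.16 (SE 0.10, adjusted p = 0.0033). AT4G29030 and AT3G57780 fell by 0.90 and 0.89. The adjusted p of these 16 genes lay between 0.00048 and 0.0464. In the limma fit, 28 of the 101 probe sets changed at least 2-fold.

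The variegated count changed with single arrays. It was 25, 16 and 44 without wild-type replicates 1, 2 and 3, it was 10, 13 and 46 without variegated replicates 1, 2 and 3, and 206 without stunted replicate 1. With the bioB spike-in signal as a covariate it was 40, of which 23 were among the 101, with 8 of the 16 genes named passing, and that signal was 6.89 ± 0.74 on the variegated and 7.81 ± 0.91 on the wild-type arrays (n = 3, exact permutation p = 0.4). All 16 genes kept their direction in every omission, and 6 of them (AT2G21640, AT5G09570, AT1G43590, AT2G33850, AT3G11880 and GH9B8) also passed in each of the 9. An unmoderated test, which has fewer degrees of freedom, ended the call of all 16, with adjusted p of 0.0513 to 0.126 for these 6. The other 10 lost the call on leaving out at least 1 of the wild-type or variegated arrays, or stunted replicate 2, with adjusted p of up to 0.178. CCS lost it without any 1 wild-type array or variegated replicate 1 or 2 (adjusted p up to 0.112).

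**Figure D1:**
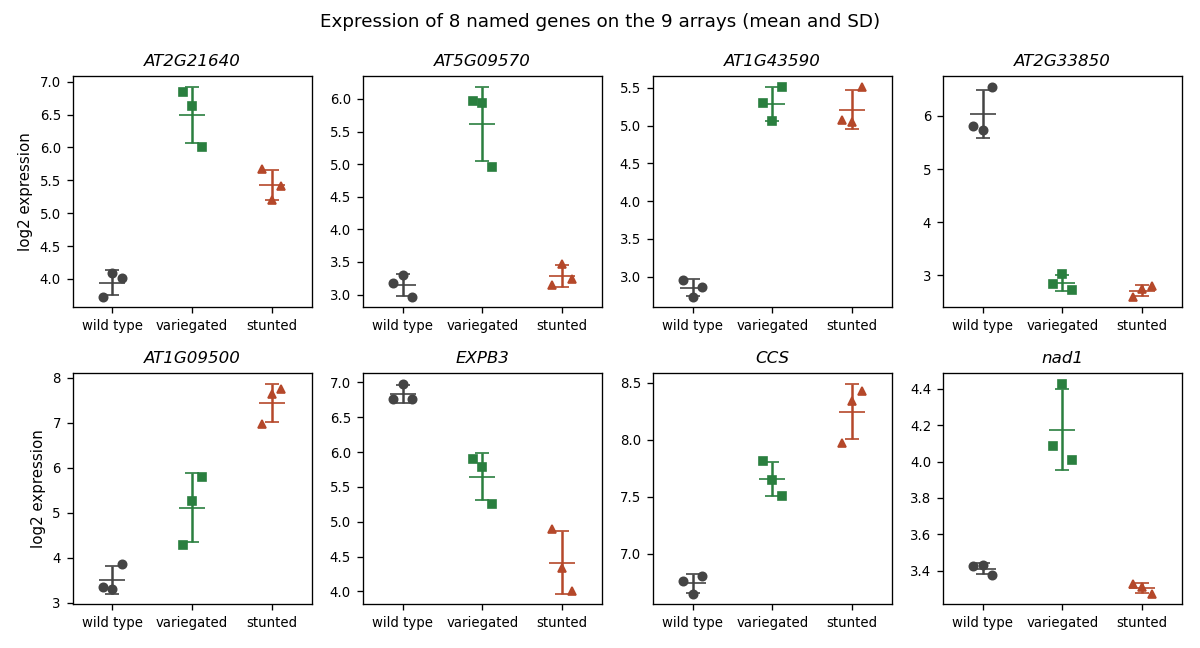
Log2 expression of 8 genes (vertical axes, separate ranges) on the 3 wild-type, 3 variegated and 3 stunted arrays. Points are arrays, and bars are the group mean and SD. AT5G09570 and nad1 are high on the variegated arrays alone, AT2G33850 is low on all 6 RNAi arrays, and AT1G09500, EXPB3 and CCS differ from wild type most on the stunted arrays.

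Mitochondrion-encoded genes rose as a list in variegated plants. All 16 had a positive change, with a median of 0.32 (camera adjusted p = 4.11e-10; adjusted p = 0.0594 with an estimated correlation). Singly, 3 rose: the cytochrome c maturation gene ccb452 by 0.99 (SE 0.11), and the complex I subunit genes nad1 by 0.76 (SE 0.10) and nad5 by 0.59 (SE 0.09). Adjusted over the list alone, 9 rose. Most members were dim, with a median level of 3.31 near the array medians. The mean over the 16 genes was 3.82 ± 0.09 on the variegated arrays and 3.4 ± 0.05 on the wild-type arrays (n = 3, exact permutation p = 0.1, the smallest possible). Of the single calls, ccb452 lost its call without variegated replicate 1 or 2 (adjusted p up to 0.0647). The call of nad1 was lost without variegated replicate 1 or any 1 wild-type array (up to 0.0814), and that of nad5 without any 1 wild-type or variegated array or stunted replicate 2 (up to 0.121).

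The alternative respiration list, of which the external NAD(P)H dehydrogenase genes NDB2, NDB3 and NDB4 were measured, was higher too (median 0.38, camera adjusted p = 0.00754; adjusted p = 0.0924 with an estimated correlation). None of the 3 passed singly over all genes and 2 did adjusted over the list alone. NDB3 had a change of 0.45 (SE 0.11, adjusted p = 0.12) and NDB4 of 0.36 (SE 0.11, adjusted p = 0.195). Without wild-type replicate 2 this list had an adjusted p of 0.0579. As fixed beforehand it also held AT2G21640, AT5G09570 and the mitochondrial heat shock protein gene AT5G51440, which were measured but left out because the reference table did not pair the listed symbols with these loci. Matched by locus code alone, a choice made after the data were seen, the 6 members had a median of 0.54, with 2 rises, or 5 adjusted over the list alone (camera adjusted p = 9.74e-09; adjusted p = 0.0297 with an estimated correlation).

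Chlorophyll synthesis genes were higher (median 0.31, camera adjusted p = 0.000232; adjusted p = 0.0924 with an estimated correlation), with HEMB1, an early enzyme of the pathway, up by 0.45 (SE 0.07, adjusted p = 0.0408), 7 members not passing, and 4 rises adjusted over the list alone. Leaving out any 1 wild-type or variegated array, or stunted replicate 2, ended the call of HEMB1 (adjusted p up to 0.148). The cell division list was lower (median -0.29, camera adjusted p = 0.00667; adjusted p = 0.0924 with an estimated correlation). None of its 4 members passed and 1 fell adjusted over the list alone. Its largest change was in SIM, an inhibitor of cyclin-dependent kinases that restrains division, at -0.77 (SE 0.13, adjusted p = 0.0516), and PRL had -0.31 (SE 0.15, adjusted p = 0.485).

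The other 16 lists gave camera adjusted p-values from 0.32 to 0.997. They were the nuclear photosystem and light harvesting genes, the Calvin cycle, plastid-encoded genes, antioxidants, endoplasmic reticulum stress, jasmonate, abscisic acid with drought and cold, gibberellin, auxin, flavonoids, flowering time, root markers, guard cell markers, senescence, touch and wounding, and cell expansion.

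In stunted plants, 1116 probe sets rose and 1081 fell against wild type, which is 9.7% of those tested, and 384 of these changed at least 2-fold. Of the 2197, 1121 mapped to no single gene, and the largest changes, 4.27 and -4.03, were not in named genes. AT1G09500, a cinnamyl alcohol dehydrogenase-like gene, rose by 3.94 (SE 0.36, 15.3-fold, adjusted p = 0.000532), from 3.51 ± 0.31 in wild type to 7.45 ± 0.42 (mean ± SD, n = 3). AT1G05340 rose by 3.13 (SE 0.28) and AT3G02480, a late embryogenesis abundant protein gene, by 2.86 (SE 0.66, adjusted p = 0.0269). AT1G43590 rose by 2.36 (SE 0.15), close to its rise in variegated plants. AT2G05540, a glycine-rich protein gene, rose by 2.28 (SE 0.33), AT3G57020, strictosidine synthase-like, by 2.08 (SE 0.10), AT1G68440 by 2.07 (SE 0.11) and AT5G39520 by 1.82 (SE 0.34). CCS rose by 1.5 (SE 0.13, adjusted p = 0.00038).

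Of the falls in stunted plants, AT2G33850 again fell most among the named genes, by 3.33 (SE 0.19, 10-fold, adjusted p = 8.03e-05). EXPB3, a beta-expansin that loosens cell walls, fell by 2.42 (SE 0.23, adjusted p = 0.000598), from 6.83 ± 0.13 to 4.41 ± 0.45 (n = 3). AT5G22580, a stress-responsive barrel-domain gene, fell by 2.37 (SE 0.22), and the lipid-transfer family genes AT1G62500 and AT5G05960 fell by 2.19 (SE 0.28) and 2.05 (SE 0.24). AT2G14900, a gibberellin-regulated gene, fell by 2.18 (SE 0.17), AT1G27030 by 2.12 (SE 0.17) and the jacalin-related lectin gene JAL23 by 2.07 (SE 0.35, adjusted p = 0.00716). Among single members of lists too small to test, the ethylene-response factor EIN3 fell by 0.46 (SE 0.08), BCAT4 of glucosinolate synthesis by 0.68 (SE 0.16), and the cytokinin response regulators ARR15 and RR16 by 0.55 (SE 0.14) and 0.62 (SE 0.16). AT5G48570, a heat-induced immunophilin, rose by 0.92 (SE 0.17). Of these 5 genes, EIN3 and AT5G48570 passed in each of the 9 single-array omissions, while RR16 lost its call in all 9 (adjusted p up to 0.116). ARR15 and BCAT4 lost theirs without any 1 wild-type array or stunted replicate 2 or 3, and ARR15 also without variegated replicate 3 (up to 0.119).

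The stunted count was 1435 without wild-type replicate 2 and 1241 without stunted replicate 2. With the actin 3' minus 5' signal as a covariate, a sign of RNA quality, it was 1412, of which 1106 were among the 2197. That signal was 1.65 ± 0.27 on the stunted and 1.26 ± 0.26 on the wild-type arrays (n = 3, exact permutation p = 0.2). Other 3' minus 5' controls were not used as covariates. The GAPDH signal was similar, at -0.16 to 0.11 on stunted and -0.17 to 0.03 on wild-type arrays. The ubiquitin signal leaned the way of actin, at -0.56 to -0.27 and -0.68 to -0.5. Of the 16 genes named, 15 passed in each of the 9 omissions and 13 in the unmoderated test. AT3G02480 lost its call without wild-type replicate 1 or 2 or stunted replicate 1 or 3, with an adjusted p of up to 0.0938.

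Genes of cell expansion and the primary wall fell as a list in stunted plants (median -0.45, camera adjusted p = 6.7e-05; adjusted p = 0.271 with an estimated correlation). Of 8 measured members, EXPB3, the expansin EXPA4 (a fall of 1.33, SE 0.22) and COB, which orients cellulose deposition (a fall of 0.83, SE 0.15), passed. Adjusted over the list alone, 7 fell. The cell division list was lower (median -0.35, camera adjusted p = 0.0145; adjusted p = 0.271 with an estimated correlation). In it SIM, the inhibitor of division, fell by 0.83 (SE 0.13, adjusted p = 0.00567), and 3 members did not pass, while the same 1 of 4 fell adjusted over the list alone. The division list had an adjusted p of 0.0668 without stunted replicate 1 and of 0.0535 without the dimmest 30% of probe sets.

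Plastid-encoded genes were higher in stunted plants as a list, with 59 of 69 above 0 and a median of 0.28 (camera adjusted p = 1.59e-05). With an estimated correlation the adjusted p was 0.651, and with fry it was 0.306. Of the 69, 9 rose, also when adjusted over the list alone, among them the ribosomal protein genes rpl16 by 1.70 (SE 0.42), rpl20 by 1.60 (SE 0.20) and rps2 by 1.34 (SE 0.29), and ycf3, a photosystem I assembly factor, by 1.22 (SE 0.25). The mean over the 69 genes was 8.27 ± 0.44 on the stunted and 7.83 ± 0.24 on the wild-type arrays, a difference no larger than the spread between arrays (n = 3, exact permutation p = 0.3). The 25S rRNA control probe set was higher on the same arrays, at 7.36 ± 2.48 against 4.96 ± 1.28 (exact permutation p = 0.2), and stunted replicate 1, with the lowest 25S signal of its group at 4.50, also had the lowest plastid mean at 7.82. Within wild type the order was the opposite, with the highest 25S signal (6.44) and the lowest plastid mean (7.58) both on replicate 3. Within variegated plants the lowest 25S signal (4.49) and plastid mean (7.63) were both on replicate 1 and the highest (8.66 and 8.17) both on replicate 3. The list's adjusted p was 0.0573 with the 25S signal as a covariate and 0.19 with the actin signal. Families within the list were uneven in this respect and are given further below. Of the 4 genes named, rpl20 passed in each of the 9 omissions. The call of rpl16 was lost without any 1 wild-type array, variegated replicate 3 or stunted replicate 2 or 3 (adjusted p up to 0.108). That of rps2 was lost without wild-type replicate 1 or 2 or stunted replicate 3 (up to 0.0719), and that of ycf3 without wild-type replicate 2 or 3 or stunted replicate 2 (up to 0.0667).

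Chlorophyll synthesis genes were higher as a list (median 0.29, camera adjusted p = 0.0145; adjusted p = 0.335 with an estimated correlation). HEMA2 rose by 0.51 (SE 0.10), GSA1 by 0.47 (SE 0.10) and HEMB1 by 0.41 (SE 0.07), all early steps of the pathway, while PORB, the light-dependent protochlorophyllide reductase, fell by 0.83 (SE 0.13, adjusted p = 0.0052). Adjusted over the list alone, 5 rose and 1 fell. GSA1 lost its call without wild-type replicate 1 or stunted replicate 2 (adjusted p up to 0.0879). The list's adjusted p was 0.0573 with the 25S signal as a covariate, 0.145 with the actin signal, 0.106 with the bioB signal and 0.0676 without the dimmest 30% of probe sets. Mitochondrion-encoded genes were higher (median 0.17, camera adjusted p = 0.0145; adjusted p = 0.405 with an estimated correlation). Here ccb382 rose by 0.65 (SE 0.18) and ccb452 by 0.62 (SE 0.11), 14 members did not pass, and 4 rose adjusted over the list alone. Leaving out wild-type replicate 2 or stunted replicate 1 ended this list's call (adjusted p up to 0.135), as did leaving out the dimmest 30% of probe sets (0.0535). The call of ccb382 was lost without wild-type replicate 2 or 3, any 1 variegated array or stunted replicate 2 or 3 (adjusted p up to 0.166), and also with quantile normalization (0.0738), median centring (0.0537) and robust moderation (0.0505).

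The other 15 lists gave camera adjusted p-values from 0.0829 to 0.904 in stunted plants. Matched by locus code, the alternative respiration list had a median of 0.16 and did not pass (camera adjusted p = 0.0582; adjusted p = 0.346 with an estimated correlation), with 1 of 6 members rising, also adjusted over the list alone. Single members that passed within the 15 lists were LHCB4.3, a light-harvesting protein, with a fall of 0.88 (SE 0.17), the jasmonate methyltransferase JMT with a fall of 1.33 (SE 0.25) and the cold-regulated COR15A with a fall of 0.95 (SE 0.25). PYK10, a beta-glucosidase in the root marker list, rose by 1.5 (SE 0.15, adjusted p = 0.000875), and WRKY6, a transcription factor in the senescence list, rose by 1.03 (SE 0.20). TPI of the Calvin cycle fell by 0.34 (SE 0.09) and PUB23 of the touch list by 0.37 (SE 0.09). LHCB4.3, JMT and PYK10 passed in each of the 9 omissions. COR15A and TPI lost the call without wild-type replicate 2 or 3, any 1 variegated array or stunted replicate 2 or 3, and COR15A also without wild-type replicate 1 (adjusted p up to 0.131). PUB23 lost it without wild-type replicate 1 or 2 or stunted replicate 2 or 3 (up to 0.0953), and WRKY6 without wild-type or stunted replicate 2 (up to 0.0577).

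**Figure D2:**
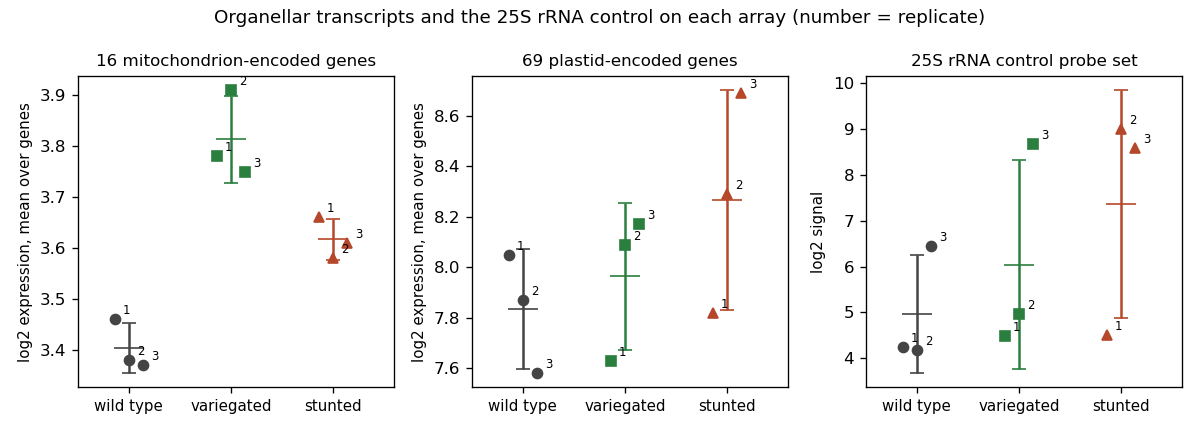
Mean log2 expression over 16 mitochondrion-encoded genes and over 69 plastid-encoded genes, and the log2 signal of the 25S rRNA control, on each of the 9 arrays (points, numbered by replicate; bars are the group mean and SD). The variegated arrays lie highest for mitochondrion-encoded genes (3.75 to 3.91), while plastid-encoded genes and the 25S control spread widely within the stunted group (7.82 to 8.69 and 4.50 to 8.99).

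Both RNAi phenotypes moved many of the same probe sets. Of the 61 that rose in variegated plants, 50 also rose in stunted plants, and of the 40 that fell, 37 also fell. Independent lists of these sizes would share 3 and 1.9. By limma, 0 probe sets passed in opposite directions, and 14 had an unadjusted p under 0.05 in both comparisons with opposite signs, against 1657 with the same sign. Unchanged groups simulated against shared wild-type arrays gave means of 6.2 and 297.6. Among the 2197 stunted calls, the variegated difference had the same sign in 94.3%, against 85.4% in the simulation for the 2197 probe sets of lowest p. Over these probe sets, chosen for passing in stunted plants, the median absolute change was 0.645 in stunted and 0.281 in variegated plants. Of the 101 variegated calls, the change was larger in stunted plants in 60 (59.4%). Across the 22746 probe sets, which are not independent replicates, the changes correlated at r = 0.665 (rho = 0.599). The simulation gave r = 0.50 and rho = 0.461. It held no real changes, which widen the spread of the differences. Its r, rho and share of equal signs are therefore not the part of the observed values that the shared arrays supply. The covariance was 0.0469 against a simulated 0.01, and the difference of 0.0369 estimates the covariance that the shared arrays do not add. Part of the excess in overlap over independent lists may come from the shared wild-type arrays, which are too few to split.

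Between the RNAi phenotypes, 198 probe sets were higher and 198 lower in stunted than in variegated plants, and 94 of them by at least 2-fold. Of the 396, 206 mapped to no single gene, and the largest rise, 2.86, was not in a named gene. AT1G09500 was higher by 2.33 (SE 0.36), AT1G05340 by 2.23 (SE 0.28) and AT2G05540 by 1.90 (SE 0.33). PYK10 was higher by 1.74 (SE 0.15, adjusted p = 0.0018), AT4G20860, a berberine bridge enzyme-like oxidase, by 1.62 (SE 0.13), the vacuolar sugar transporter SWEET2 by 1.42 (SE 0.21), and AT3G28270 and AT1G68440 both by 1.40. AT5G09570, the mitochondrial cysteine-rich protein, changed by -2.34 (SE 0.24, adjusted p = 0.00361), and its stunted level of 3.28 ± 0.17 lay near the wild-type 3.14 ± 0.17 (n = 3). AT2G07722 showed the same pattern with a change of -1.26 (SE 0.19). AT5G22580 changed by -1.90 (SE 0.22), the lipid-transfer family genes AT5G55450 and AT1G62500 by -1.49 (SE 0.22) and -1.37 (SE 0.28), the gibberellin-regulated AT2G14900 by -1.48 (SE 0.17), AT3G28500 by -1.34 (SE 0.15) and the drought-induced DI21 by -1.27 (SE 0.08).

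This count was 212 without wild-type replicate 2, it was 48, 117 and 184 without variegated replicates 1, 2 and 3, and 1404 and 85 without stunted replicates 1 and 2. With the actin 3' minus 5' signal as a covariate it was 79, of which 52 were among the 396, and 6 of the 16 genes named passed. That signal was 1.65 ± 0.27 on the stunted and 1.15 ± 0.26 on the variegated arrays (n = 3, exact permutation p = 0.2). Of the 16 genes named, 7 passed in each of the 9 omissions and 4 in the unmoderated test, and all 16 kept their direction. The other 9 lost the call without at least 1 wild-type or variegated array or stunted replicate 2 or 3, with adjusted p of up to 0.193.

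For lists, 5 of the 10 splits of these 6 arrays into 3 and 3, the real one included, gave as many camera calls. With fry no list passed, so the list calls between the phenotypes are weak. The cell expansion list was lower in stunted than in variegated plants (median -0.54, camera adjusted p = 6.21e-05; adjusted p = 0.473 with an estimated correlation and 0.0582 with fry). Here EXPB3 changed by -1.23 (SE 0.23, adjusted p = 0.0332) and EXPB1 by -0.55 (SE 0.10), 6 members did not pass, and 6 fell adjusted over the list alone. EXPB3 lost its call without any 1 wild-type array, variegated replicate 1 or 2 or stunted replicate 2 or 3 (adjusted p up to 0.149), and EXPB1 without wild-type replicate 2, any 1 variegated array or stunted replicate 2 or 3 (up to 0.094). Mitochondrion-encoded genes were lower (median -0.15, camera adjusted p = 0.00375; adjusted p = 0.473 with an estimated correlation). Only nad1 of the 16 passed, here and adjusted over the list alone, with a change of -0.87 (SE 0.10, adjusted p = 0.00684), a call lost with the actin covariate (adjusted p = 0.066) and in the unmoderated test (0.0798). Plastid-encoded genes were higher (median 0.29, camera adjusted p = 8.99e-06; adjusted p = 0.789 with an estimated correlation), and none of the 69 passed in limma, here or adjusted over the list alone, while 6 had an unadjusted p under 0.05. Their call ended without variegated replicate 1 or stunted replicate 3 (adjusted p up to 0.141) and with the actin signal as a covariate (adjusted p = 0.853). The actin covariate also ended the call for mitochondrion-encoded genes (adjusted p = 0.0803). The alternative respiration list matched by locus code was lower in stunted than in variegated plants (median -0.29, camera adjusted p = 0.000345; adjusted p = 0.26 with an estimated correlation), with 2 of 6 members falling, or 4 adjusted over the list alone. The other 17 lists gave adjusted p-values from 0.0533, for the nuclear photosystem genes, to 0.86. PORB of the chlorophyll list, which was not called, changed by -0.64 (SE 0.13, adjusted p = 0.0474), and lost this call without wild-type replicate 2, any 1 variegated array or stunted replicate 2 or 3 (adjusted p up to 0.162).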

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

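The covariate tests of the organelle gene means below were chosen after the array values had been seen, and the other tests before their results were seen.

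Only genes picked by the naming rule, applied to lists and families alike, were searched, and not all genes. In 8 of them the change against wild type had opposite signs in the 2 RNAi phenotypes and the stunted against variegated difference itself passed in limma. As 0 probe sets passed against wild type in opposite directions, at least 1 of the 2 changes did not pass in each gene. PYK10 differed by 1.74 (-0.24 in variegated, 1.5 in stunted plants), AT3G28270 by 1.40 (-0.82 and 0.58) and ATG8B, an autophagy gene, by 0.44 (-0.29 and 0.15). DI21 differed by -1.27 (0.33 and -0.94), CML41, a calmodulin-like gene, by -1.06 (0.81 and -0.25), nad1 by -0.87 (0.76 and -0.11), the tetraspanin gene TET7 by -0.81 (0.02 and -0.79) and EXPB1 by -0.55 (0.30 and -0.25). Their adjusted p-values lay between 0.000306 and 0.0315. PYK10, DI21 and nad1 passed in each of the 9 single-array omissions, but nad1 lost its call in an unmoderated test (adjusted p = 0.0798) and with the actin covariate (0.066). ATG8B lost its call without wild-type replicate 2 or 3, any 1 variegated array or stunted replicate 2 or 3, and CML41 without wild-type replicate 2, any 1 variegated array or stunted replicate 3 (adjusted p up to 0.133 for both). EXPB1 lost it without wild-type replicate 2, any 1 variegated array or stunted replicate 2 or 3 (up to 0.094), AT3G28270 without variegated replicate 1 or 2 or stunted replicate 2 (up to 0.0748), and TET7 without variegated replicate 1 (0.0818). PYK10 is abundant in roots, while the tissue was above-ground, and the 2 other measured root markers did not pass.

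Outside the main measurement, the 25S rRNA control probe set exceeded the highest wild-type value of 6.44 on 3 RNAi arrays, with 8.66 on variegated replicate 3, 8.99 on stunted replicate 2 and 8.58 on stunted replicate 3. The other 3 RNAi arrays lay between 4.49 and 4.97.

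The higher level of plastid-encoded transcripts in stunted plants was set against that control, on which their mean had a slope of 0.085 (SE 0.061). Within wild type the array with the highest 25S signal, 6.44, had the lowest plastid mean, 7.58, while the array with the lowest 25S signal also had the lowest plastid mean within variegated (4.49 and 7.63) and stunted plants (4.50 and 7.82). The mean over the 69 genes differed by 0.43 (SE 0.27) from wild type, by 0.23 (SE 0.29) with the 25S signal as a covariate, and by 0.21 (SE 0.33) with the actin 3' minus 5' signal. The difference was within 2 SE of 0 before any correction, so neither explanation can be told apart from the group with 3 arrays each, and a carry-over of non-polyadenylated RNA into the labelled material and a change in plastid transcripts in stunted plants both stay open.

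The rise of mitochondrion-encoded transcripts in variegated plants went against 2 technical explanations, each in the narrow form tested. With the 25S signal as a covariate the difference of the mean over the 16 genes was 0.43 (SE 0.04), against 0.41 (SE 0.05) without it. The median change of 0.32 lay at percentile 100 of 10000 random gene lists matched on level, whose highest was 0.19. This argues against a drift common to probe sets of that level. The random lists were drawn gene by gene, so they cannot decide on a drift shared only by members that vary together. Hybridisation of transcripts from the nuclear copy of the mitochondrial genome was not tested and stays open, as does a biological difference tied to the variegated phenotype.

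The many calls in stunted plants were weighed against RNA quality. Over the 2197 called probe sets, a median share of 0.95 of the change was left with the actin 3' minus 5' covariate (quartiles 0.82 and 1.07) and 0.94 with the 25S covariate (quartiles 0.84 and 1.04). These probe sets were chosen for passing, that is for a difference large beside the spread within groups. Both signals spread widely within groups (actin 1.65 ± 0.27 on stunted and 1.26 ± 0.26 on wild-type arrays, 25S 7.36 ± 2.48 and 4.96 ± 1.28). A change that followed such a signal alone would hardly have passed. The shares therefore cannot decide on RNA quality, which stays open. A covariate also takes a degree of freedom and is partly shared with the groups, and the counts were 1412 and 1631. The biological difference between stunted and wild-type plants stays open, untested beyond the comparison itself.

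The 6 arrays of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. For probe sets, the real split gave 101, 2197 and 396 in the 3 comparisons, and the highest other split gave 0 in each by limma. At an unadjusted p under 0.05 the real split gave 2633, 5118 and 3504, and the highest other 1625, 2215 and 2528. In each, 1 split, the real one, gave as many. Every other split mixes arrays of both groups, so a difference between the groups, whatever its source, adds to the residual spread. Low counts in the other splits are thus partly built in and do not separate the phenotype from a technical difference. For lists, the real split gave 4, 5 and 3, and the highest other split gave 3, 4 and 5. As many lists came from 1, 1 and 5 of the splits. The number of lists called between the phenotypes was therefore not particular to the real split.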

How the results depend on the processing

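The covariates and the list members matched by locus code alone were chosen after the data were seen. No named gene or list call reversed under any alternative run. The counts for variegated against wild type, stunted against wild type and stunted against variegated plants, in that order, were 28, 384 and 94 with a 2-fold minimum, 8, 850 and 56 at an adjusted p under 0.01, 206, 1321 and 133 with only the compared groups fitted, and 1, 797 and 32 with an unmoderated test, which has fewer degrees of freedom. Array weights gave 349 and 1028 for the comparisons with few calls, and the actin covariate gave 186, 1412 and 79. For variegated against wild type alone, the 25S covariate gave 155 and the bioB covariate 40. Leaving out 1 array gave 10 to 206, 1241 to 2955 and 48 to 1404. Apart from the degrees of freedom, the cause was not tested. Centring, quantile normalization, the intensity trend, robust moderation, the dim filter and the removal of cross-hybridising probe sets kept each count within 1.5 times.

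Same-numbered arrays deviated together weakly or not at all (r from 0 to 0.28 over 9 pairs), and not every array correlated best with its own number. Between groups, replicates 1 and 3 deviated in opposite directions (r from -0.28 to -0.07). Deviations were taken from each group's own mean, so positive values for equal numbers force negative ones elsewhere, and this is no separate sign. The leading principal component also rose from replicate 1 to replicate 3 in each group. An effect shared by arrays of the same number was therefore not excluded, and the main fit did not model it. With the replicate number as a block the counts were 191, 2889 and 940, the lists passing 4, 5 and 4, and the correlation of changes 0.665. These counts exceed the 101, 2197 and 396 of the main fit, although a block takes degrees of freedom.

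With an estimated correlation, camera called 0 lists in each comparison (4, 2 and 2 at an unadjusted p under 0.05), and fry called 0 for stunted against variegated (5 unadjusted). Dropping the dimmest 30% left 2 lists in stunted against wild type. The naming rule, applied over all lists and families, picked 154 gene results that passed, not all of which are described here. Of these, 90 still passed with the actin covariate, 126 with 25S, 119 with bioB, 107 with only the compared groups and 52 with the unmoderated test. Matching by locus code gave 5 lists for stunted against variegated, adding alternative respiration and the nuclear photosystem genes. Over 20 alternatives each, the adjusted p of the mitochondrion-encoded list in variegated plants lay between 1.4e-10 and 0.0594, that of the plastid-encoded list in stunted plants between 2.86e-11 and 0.651, and that of chlorophyll synthesis in stunted plants between 0.0105 and 0.335. Between the phenotypes these limits were 1.37e-12 and 0.853 for plastid-encoded and 0.000722 and 0.473 for mitochondrion-encoded genes. Leaving out 1 array moved the correlation from 0.594 to 0.707. The alternatives for MSH1 were not run. Dim genes near the floor limit what small changes can be read.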

Other observations

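The single-array omissions and covariates for the families below were chosen after the data were seen. Families of related genes, defined by symbol after the gene table had been opened and before any difference was computed, added further groups. Of 7 tubulin genes measured, 5 fell in stunted plants against wild type, among them TUB1 by 1.31 (SE 0.20, adjusted p = 0.00414) and TUB7 by 0.8 (SE 0.11; camera adjusted p for the family = 0.000218, adjusted p = 0.307 with an estimated correlation). TUA1, named after its values were seen, rose by 0.57 (SE 0.15) and lost its call without wild-type, variegated or stunted replicate 2, wild-type or variegated replicate 1 or stunted replicate 3 (adjusted p up to 0.16), and with the actin (0.215), bioB (0.103) and 25S covariates (0.0846). The tubulin family was also lower in variegated than in wild-type plants (median -0.29, camera adjusted p = 0.0466; adjusted p = 0.751 with an estimated correlation), where the 7 members had adjusted p-values of 0.118 to 0.983 over all genes and 3 fell adjusted over the family alone. That call ended without wild-type replicate 3, variegated replicate 2 or stunted replicate 2 (adjusted p up to 0.324). Between the phenotypes the family was lower in stunted plants (median -0.4, camera adjusted p = 0.00153; adjusted p = 0.321 with an estimated correlation). The families that follow are given for stunted against wild-type plants. Plastid-encoded families were uneven. The 11 genes of RNA polymerase, accD, clpP, matK, ycf3, ycf4, ccsA and cemA had a median of 0.65 (camera adjusted p = 0.000491; adjusted p = 0.471 with an estimated correlation). They kept the call in each omission and with each covariate (up to 0.0253). The 25S and actin covariates ended the calls of the ribosomal protein and the cytochrome b6f, ATP synthase and rbcL families. Photosystem II had a median of 0.16 and did not pass. Of 15 endoglucanases of family GH9, 4 fell, with GH9B8 falling by 1.98 (SE 0.10) and GH9B13 by 1.16 (SE 0.13; camera adjusted p = 0.015, adjusted p = 0.398 with an estimated correlation). Of 18 expansins 4 fell, adding EXPA16 with a fall of 1.16 (SE 0.14) and EXLB1 with a fall of 1.09 (SE 0.20) to the members named before (camera adjusted p = 0.00138, adjusted p = 0.453 with an estimated correlation). The RALF-like signal peptide genes RALFL34 and RALFL31 fell by 0.78 (SE 0.07) and 0.65 (SE 0.10), the 2 that passed of 11 (camera adjusted p = 0.0464, adjusted p = 0.453 with an estimated correlation). Of 12 ubiquitin-conjugating enzyme genes 3 fell, led by UBC22 with a fall of 0.61 (SE 0.07; camera adjusted p = 0.032, adjusted p = 0.453 with an estimated correlation). The call of the RALF-like family ended without wild-type replicate 1 or 2 or stunted replicate 3 (adjusted p up to 0.189), and that of the ubiquitin-conjugating family without wild-type replicate 1 or 3 or stunted replicate 2 (up to 0.131). Each of the 3 covariates also ended both calls (up to 0.325). With the actin covariate the GH9 and expansin families had adjusted p-values of 0.0615 and 0.0785.

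Among 17 measured nuclear genes for organelle RNA editing and photosystem assembly, 4 rose in stunted plants against wild type, 13 did not pass, and 11 of the 17 had a positive change (median 0.19, camera adjusted p = 0.00496; adjusted p = 0.398 with an estimated correlation). OTP84 rose by 0.51 (SE 0.08) and passed in each of the 9 single-array omissions. CRR21 rose by 0.98 (SE 0.26) and CRR22 by 0.48 (SE 0.11), and both lost the call without any 1 array other than stunted replicate 1 (adjusted p up to 0.15). LPA1 rose by 0.68 (SE 0.16) and lost it without wild-type replicate 1 or 2, variegated replicate 2 or stunted replicate 2 or 3 (up to 0.109). By camera with an estimated correlation, none of the 38 families passed in any of the 3 comparisons (4, 2 and 4 at an unadjusted p under 0.05 for stunted against wild type, variegated against wild type and stunted against variegated), where the lowest adjusted p was 0.307 for stunted and 0.751 for variegated plants against wild type, and 0.321 between them.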
